A study of Homo sapiens with 3 samples.

How the data were processed

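RNA of 22Rv1 cells was collected after transfection with MLPH transcript V1, MLPH transcript V4 or the empty vector, with 1 sample per group. Per the labels' protocols, poly(A) RNA was enriched and sequenced as 150 bp single-end reads on a HiSeq2500. The deposited table holds whole-number read counts per gene symbol, which the authors made from reads on build hg19, per the submitters' processing notes. The aligner, the counting program, its annotation, its strand setting and its treatment of reads that match several genes or transcripts are not given in the sources used here. The series' design text mentions a technical replicate for each line. The table has 1 column per line, and whether repeat runs were summed is not given in the sources used here.

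Columns were tied to samples by name alone. The columns named for V1 and V4 matched 1 sample title each. The remaining column (columns not used: 1) names no transfection, and taking it as the empty-vector sample would have rested on elimination, so it was used in no step. The 2 comparisons over the empty vector and the agreement of both ratios over that control, which were planned, were therefore not run. The filter on low counts, planned over 3 libraries, was applied over the 2 compared. Scaling factors, planned over 3 libraries, came from the 2 as well.

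The table had 15512 rows. Counts of 21 symbols on more than 1 row were summed. Another 22 rows carried a calendar date in place of a symbol and were kept apart without a name. In 1779 rows both libraries had 0 counts. Genes were kept at a mean CPM of at least 1 over both libraries, which left 8840 genes holding 99.8% of V1 counts and 99.9% of V4 counts. Total counts were 9253399 (V1) and 9609381 (V4), and the median count of a kept gene was 154 and 155. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

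Library sizes were scaled by TMM in edgeR 4.0.16 under R 4.3.3, with factors of 1.01 (V1) and 0.988 (V4). Log2 ratios used a prior count of 2 scaled to library size. Each ratio got a 95% exact (Clopper-Pearson) conditional binomial interval from scipy 1.17.1. With 1 library per group, no test across samples was possible, no p-value across genes was computed, and each ratio describes the pair of libraries, not the conditions. Genes were counted at a ratio (with the prior) of 2 or more in either direction whose interval excluded 1. A fold against 0 counts was computed against a floor of 3 counts in that library and is given as at least that fold. The floor takes the count of the other library as exact, so the 95% interval bound is a smaller fold. Printed folds are ratios of scaled counts without the prior.

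Gene lists and cell type markers, 47 in all, were fixed before the data were examined. Members were matched by symbol, or by an older symbol that belonged to 1 current gene. The median log2 ratio of a list with at least 5 kept members was placed among 10000 random lists of the same size, matched on mean log2 CPM in 20 bins, and a median outside the central 95% of them was said to stand apart. Members were counted at 1.5-fold or more (with the prior) with an interval that excluded 1. The genes named in the text were MLPH, the 5 genes with the highest and the 5 with the lowest ratio by the interval bound nearest 1, and for each list up to 4 kept members with the largest absolute log2 ratio plus the most abundant. Some genes that this rule takes are not reported here. UCHL1 and the essential genes named in the closing section were chosen after their values were seen.

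The procedure was tested on simulated data. Poisson counts were drawn for the 8840 genes from the means and library sizes of this comparison, with 200 genes changed. Of 100 genes changed 4-fold, 99% were called, and of 100 changed 8-fold, 100%. Of the 8640 unchanged genes, 0.486% were called. The same draw without changed genes, run 100 times, gave the numbers for unchanged libraries.

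Transcript length and GC content came from the longest transcript per gene name in GENCODE v29 (GRCh38), and the number of curated transcripts from a RefSeq gene table on GRCh38. Because these differ in build from hg19, no coordinates are given. A length was found for 95.4% of kept genes and a RefSeq transcript number for 95.0%. Trends were fitted by lowess (statsmodels 0.14.6, fraction 0.3). Alternatives planned before the data were examined were DESeq2 1.42.0 median-of-ratios factors, total counts, upper-quartile scaling, other filters, prior counts of 0.5 and 8, thresholds of 1.5-fold and 3-fold, no condition on the interval, thinning to the smallest total, and unmatched random lists. Removing a length or GC trend, and keeping genes with 1 RefSeq transcript, were added after the data were examined. Figures were drawn with matplotlib 3.10.9.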

Results

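22Rv1, a human prostate cancer cell line, was transfected for 48 h with 20 μg of a plasmid carrying transcript V1 or transcript V4 of MLPH, or with the empty vector. MLPH encodes melanophilin, an adaptor that links the small GTPase Rab27a to the motor myosin Va in the transport of melanosomes. Poly(A) RNA was sequenced, and the values are read counts per gene symbol. The series has 3 samples, 1 per group. Only the V1 and V4 libraries entered a comparison, because the remaining column of the table could not be tied to a sample by its name. The comparisons over the empty vector were not run. The total was 9253399 counts in the V1 library and 9609381 in the V4 library. By counting error alone, a gene at 0 counts could have a level of up to 0.324 CPM (counts scaled to the library total) in the V1 library and 0.312 CPM in the V4 library. These bounds do not cover reads that the counting left out. Each group had 1 library, so no difference below has a replicate check and no test across samples was possible. Every interval is a 95% exact (Clopper-Pearson) conditional binomial interval of counting error. It does not cover differences between cultures, library preparation or amplified copies of the same molecule.

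MLPH was read first, because it was the transfected gene. It had 7219 counts (780 CPM) in the V1 library and 7773 counts (809 CPM) in the V4 library. The ratio of V4 over V1 was 1.06, with an interval from 1.03 to 1.10 that does not cover reads the counting left out. Both libraries received an MLPH plasmid, and gene-level counts do not separate the transcripts, so this value does not check which library received which plasmid. GENCODE v29 places MLPH on chromosome 2 and lists 23 transcripts of it.

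The V4 over V1 comparison asked how gene expression differed between cells given each transcript. The 5 genes farthest apart, ranked by the interval bound nearest 1, were lower in the V4 library. LCN2, which encodes the secreted iron-siderophore carrier lipocalin 2, had 1359 counts in the V1 library and 6 in the V4 library, 229.6-fold lower (interval 105 to 627). The fibrillar collagen genes COL1A2 and COL3A1 had 976 and 526 counts in the V1 library against 4 and 0 in the V4 library. COL1A2 was 247-fold lower (interval 96.3 to 909.8) and COL3A1 at least 178-fold lower, with a floor of 3 counts. The interval of COL3A1 reached up to -7.17 on the log2 scale, a smaller fold than the floor gives. MMP14, a membrane-bound matrix metalloproteinase, went with them at 496 counts against 3, 168-fold lower in the V4 library (interval 57.0 to 816). AKR1B1, the aldose reductase gene, had 376 counts against 3, 127-fold lower in the V4 library (interval 43.1 to 619).

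Genes higher in the V4 library had smaller gaps and low counts. MYH1, a skeletal muscle myosin heavy chain, had 3 counts in the V1 library and 56 in the V4 library, a ratio of 18.4 (interval 5.98 to 92.0). MMEL1, a membrane metalloendopeptidase, had 1 count against 20, a ratio of 19.7 (interval 3.16 to 818). POLQ, which encodes DNA polymerase theta, and SHISA3 each had 2 counts against 21, a ratio of 10.4 (interval 2.53 to 91.1). ADAM22 had 4 counts against 29, 7.15-fold higher (interval 2.51 to 28.0).

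Among 8840 kept genes, 186 were at least 2-fold higher and 379 at least 2-fold lower in the V4 library with an interval that excluded 1. At 5-fold the numbers were 6 higher and 100 lower, and at 10-fold 1 higher and 64 lower. These numbers, and those of list members at 1.5-fold, use ratios with a prior count of 2, which draws low counts toward a ratio of 1. The folds printed for single genes do not, so a gene such as MMEL1 can have a printed fold over 10 and not be counted there. In 100 simulated pairs of unchanged libraries of these depths, the highest numbers were 34 higher and 35 lower at 2-fold. At a mean CPM of at least 10, the counts were 12 higher and 58 lower, so most of the genes at least 2-fold apart lay at low levels.

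**Figure D1:**
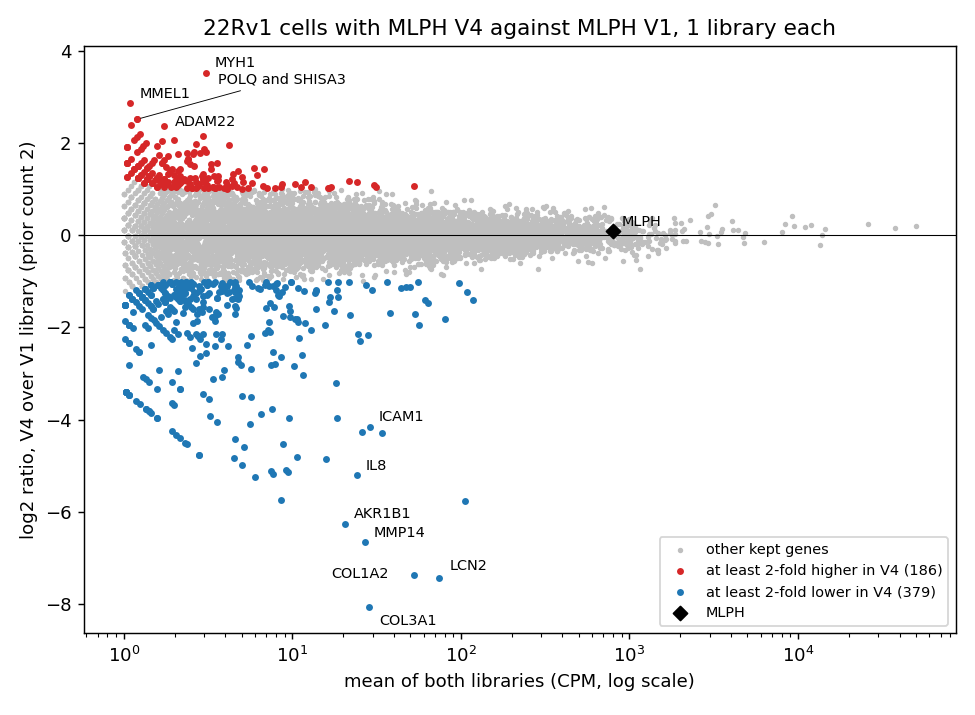
Each point is 1 of the 8840 kept genes, with the mean CPM of the V1 and V4 libraries on a log axis and the log2 ratio of V4 over V1 (prior count 2) on the vertical axis. Red and blue points are the 186 genes at least 2-fold higher and the 379 at least 2-fold lower in the V4 library, and the blue points reach farther from 0, down to -8.05 for COL3A1.

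Of the 47 gene lists fixed before the data were examined, 40 had at least 5 kept members. The median log2 ratio of 14 lists lay below, and that of 6 above, the central 95% of 10000 random lists matched on expression. Chance alone would place 2 of 40 independent lists outside. These lists share members, and genes of a pathway vary together, so the percentile describes these libraries only.

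NF-kappaB and inflammatory targets stood farthest apart. Of 13 kept members, 10 were at least 1.5-fold lower in the V4 library, 1 was higher and 2 were neither. The median log2 ratio was -3.07, at percentile 0, and -2.68 with members at 0 counts set to the floor. IL8, the neutrophil chemokine also named CXCL8, had 435 counts in the V1 library and 10 in the V4 library, 44.1-fold lower (interval 23.8 to 92.6). The chemokine gene CXCL2 had 92 counts against 1, 93.3-fold lower in the V4 library (interval 16.3 to 3724). IER3, a stress-induced survival gene, was 20.9-fold lower (interval 14.4 to 31.5), and the adhesion molecule gene ICAM1 was 19.1-fold lower (interval 13.0 to 29.3). NFKBIA, the NF-kappaB inhibitor and the most abundant member, was 2.06-fold lower (interval 1.87 to 2.28).

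Mesenchymal and invasion genes had 7 of 14 kept members lower and 0 higher, with a median of -0.67 at percentile 0.02. Besides MMP14, the matrix gene SPARC was 18.8-fold lower (interval 9.68 to 41.9), the integrin gene ITGB3 6.93-fold lower (interval 2.92 to 20.0), and SNAI1, a repressor of E-cadherin, 3.45-fold lower (interval 1.91 to 6.60). MMP10, the most abundant member, had 874 counts against 916, with an interval that included 1. Of the 3 kept markers of fibroblasts, COL1A2 and COL3A1 were lower, and LUM had 33 counts in the V1 library and 44 in the V4 library. TGF-beta targets and regulators had 5 of 15 members lower, among them TGFBI by 36.0-fold (interval 18.0 to 84.2). COL4A1, at 52 counts against 0, was lower by at least 17.6-fold against the floor (log2 interval bound -3.79). The median of that list, -0.13, lay inside the random range (percentile 10.8).

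Hippo YAP targets had 6 of 14 kept members lower and a median of -0.45 (percentile 0.09). FJX1 had 136 counts against 2, 68.9-fold lower in the V4 library (interval 18.7 to 575), and the matricellular gene CYR61 was 2.78-fold lower (interval 2.44 to 3.17). CYR61 is also an immediate early gene. That list had 3 of 22 members lower and a median of -0.28 (percentile 0.01), with the AP-1 subunit gene FOSL1 5.65-fold lower (interval 2.5 to 15.0) and IER5 2.03-fold lower (interval 1.78 to 2.31). MAPK output genes had 4 of 11 members lower and a median of -0.28 (percentile 0.83), among them PHLDA1 at 3.56-fold (interval 3.15 to 4.04) and DUSP5, an ERK phosphatase, at 2.18-fold (interval 1.89 to 2.53). CCND1, the cyclin D1 gene and the most abundant member of the MAPK list, was 1.15-fold higher (interval 1.10 to 1.19). With a GC trend removed the MAPK list was at the edge of the range (percentile 2.53).

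Antigen presentation genes had 4 of 11 kept members lower and a median of -0.34 (percentile 0.26). The class I gene HLA-B was 2.43-fold lower (interval 1.85 to 3.23). The immunoproteasome subunit gene PSMB9 was 5.45-fold lower (interval 2.53 to 13.4), the peptide transporter gene TAP2 2.76-fold lower (interval 1.58 to 5.03), and HLA-C, the most abundant, 1.48-fold lower (interval 1.42 to 1.54). HLA genes are close copies of each other, and how reads common to them were assigned is not given in the sources used here. Among genes with 1 RefSeq transcript the list was inside the range (percentile 4.06). Interferon-stimulated genes as a list did not stand apart, with a median of -0.05 (percentile 34.9) and 2 of 16 members lower. HERC5 was 4.63-fold lower (interval 2.93 to 7.62), and ISG15, the most abundant, 1.16-fold lower (interval 1.11 to 1.20). The 10 kept genes of cytosolic DNA and RNA sensing had a median of -0.14 (percentile 19.8) and 3 members lower.

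Epithelial genes had 3 of 18 kept members lower and a median of -0.21 (percentile 0.22). Among them were the keratin gene KRT7, 9.70-fold lower (interval 6.72 to 14.4), and the tight junction gene CLDN1, 8.85-fold lower (interval 5.68 to 14.5). The E-cadherin gene CDH1, the most abundant member, was 1.27-fold higher (interval 1.23 to 1.31), and GRHL2 was 1.41-fold higher (interval 1.33 to 1.5). With a GC trend removed the median moved inside the random range (-0.08, percentile 11.4).

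Androgen receptor targets lay on the other side, with a median of 0.30 (percentile 99.4). Of 15 kept members, 2 were at least 1.5-fold higher, 1 lower and 12 neither. TPD52 was 2.42-fold higher (interval 1.49 to 4.08) and FKBP5, a co-chaperone of steroid receptors, 1.90-fold higher (interval 1.34 to 2.71). ALDH1A3 was 7.79-fold lower (interval 4.61 to 14.1). The median of genes repressed by the androgen receptor also lay above the random range, at 0.35 (percentile 98.4), with 1 of 7 kept members at least 1.5-fold higher and 6 neither. TMEFF2 was 1.87-fold higher (interval 1.34 to 2.62). The target list, whose median transcript length was 4909 bases, was no longer apart at a mean CPM of at least 10 (percentile 75.6) or with a transcript length trend removed (median 0.20, percentile 97.3), and the repressed list was not apart with a GC trend removed (percentile 92.3). The 5 kept markers of luminal prostate epithelium had a median of 0.12 (percentile 81.4).

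The 5 kept neuroendocrine markers had a median of 0.50 (percentile 99.95), with 0 of 5 at least 1.5-fold apart. SCG2, a secretory granule gene, was 1.48-fold higher (interval 1.24 to 1.77) and CHGB, a granule protein gene, 1.42-fold higher (interval 1.29 to 1.57). ENO2, the most abundant, had 2735 counts against 2831. Mitosis and G2/M genes had a median of 0.24 (percentile 99.1) and 0 of 17 members 1.5-fold apart. The spindle kinesin gene KIF11 was 1.48-fold higher (interval 1.29 to 1.70) and CENPF 1.37-fold higher (interval 1.21 to 1.56). That list was inside the range with a GC trend removed (0.11, percentile 89.3) and among genes with 1 RefSeq transcript (percentile 96.4). S phase and DNA replication genes had a median of 0.02 (percentile 62.3), also with 0 of 24 members apart. The 12 mitochondrially encoded genes had a median of 0.21 (percentile 99.8) and made up 13.5% of counts in the V1 library and 15.4% in the V4 library. ND4L was 1.57-fold higher (interval 1.55 to 1.60). Against unmatched random lists their median was inside the range (percentile 96.3). Exocytosis and vesicle fusion genes, at 0.13 (percentile 97.7), were inside the range under 5 of 8 other settings.

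**Figure D2:**
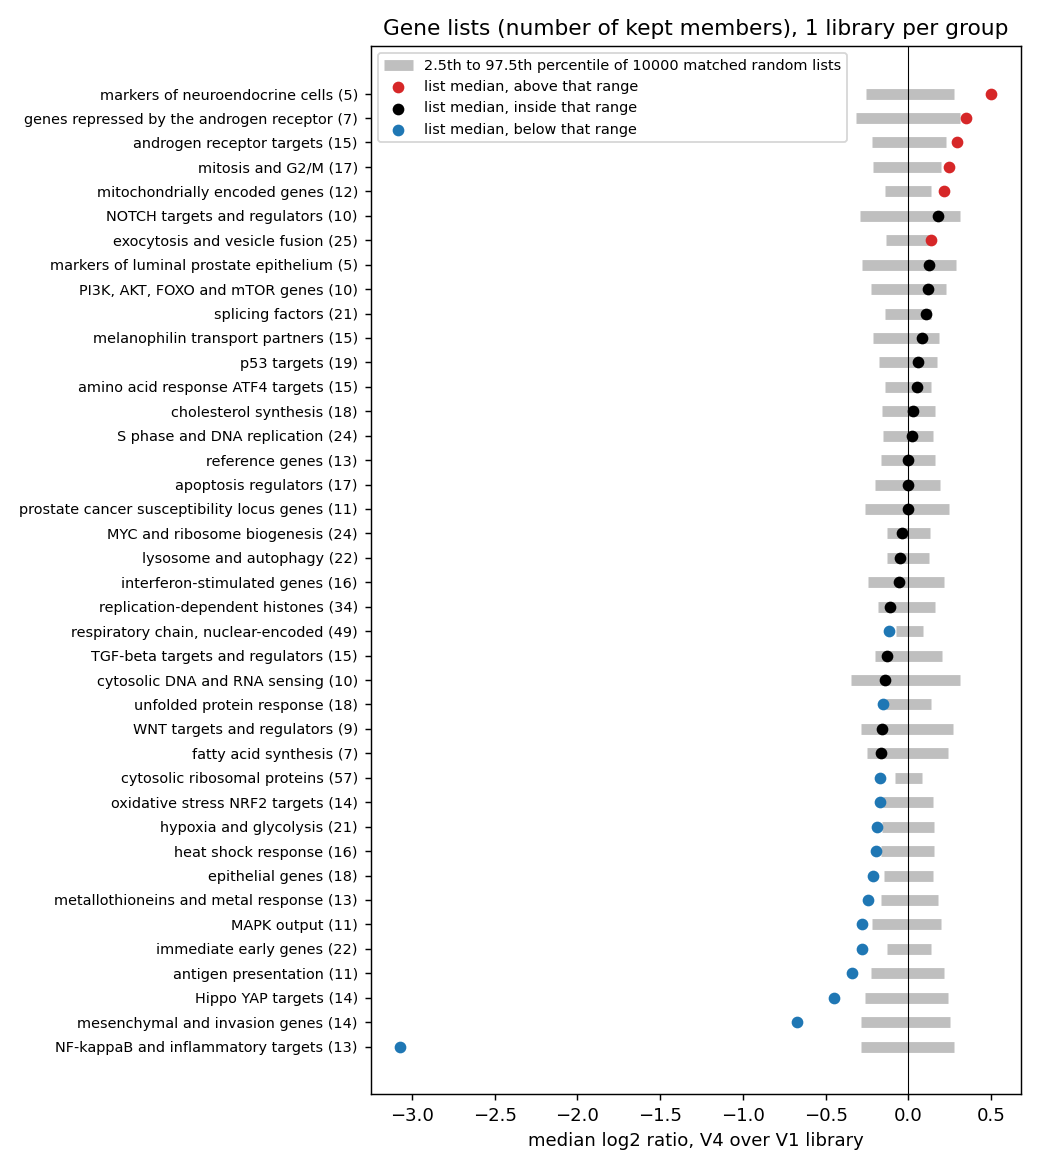
Each point is the median log2 ratio of V4 over V1 of 1 gene list with at least 5 kept members (number in brackets), and the grey bar is the central 95% of 10000 random lists matched on expression. Blue medians (14 lists) lie below and red medians (6 lists) above their bar, and NF-kappaB and inflammatory targets lie farthest from 0 at -3.07.

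Several lists of housekeeping and stress genes stood slightly apart on the low side. Cytosolic ribosomal protein genes had a median of -0.17 (percentile 0), with 3 of 57 members at least 1.5-fold lower. RPS6, the most abundant, was 1.09-fold lower (interval 1.07 to 1.11), and its direction turned with a transcript length trend removed (0.01 on the log2 scale). Nuclear-encoded respiratory chain genes had a median of -0.12 (percentile 0.20), which moved to -0.02 (percentile 16.9) with that trend removed. Heat shock genes had a median of -0.19 (percentile 0.98), with the inducible HSPA6 2.35-fold lower (interval 1.75 to 3.19). The length trend ended that call too (percentile 2.73). For metallothioneins and metal response genes the median was -0.24 (percentile 0.18), with MT1A 3.52-fold lower (interval 2.09 to 6.21) and the ferritin light chain gene FTL 1.67-fold lower (interval 1.62 to 1.71). That list was inside the range with the length trend removed (percentile 11.8) and with a GC trend removed (percentile 3.08). Oxidative stress NRF2 targets had a median of -0.17 (percentile 1.39), and SRXN1 was 1.81-fold lower (interval 1.62 to 2.02) while the cystine transporter gene SLC7A11 was 1.70-fold higher (interval 1.55 to 1.87). The NRF2 call ended with the length trend removed (percentile 4.57). Hypoxia and glycolysis genes had a median of -0.19 (percentile 1.13). They were inside the range at a mean CPM of at least 10 (percentile 7.09) and among genes with 1 RefSeq transcript (percentile 9.64). Unfolded protein response genes had a median of -0.15 (percentile 1.12). That call ended with a GC trend removed (percentile 4.69) and among genes with 1 RefSeq transcript (percentile 7.06). SDF2L1, an endoplasmic reticulum chaperone gene, was 1.52-fold lower (interval 1.43 to 1.62). Of the 14 lists on the low side, 8 stood apart against unmatched random lists too, and those that did not were the respiratory chain, heat shock, metallothionein, NRF2, hypoxia and unfolded protein lists.

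Melanophilin transport partners did not stand apart, with a median of 0.08 (percentile 80.5) and 13 of 15 kept members neither higher nor lower. RAB38, which encodes a GTPase of melanosome biogenesis, had 38 counts in the V1 library and 0 in the V4 library. It was at least 12.8-fold lower against the floor (log2 interval bound -3.31). RAB3B was 1.78-fold higher (interval 1.02 to 3.20) and MYO5B, a myosin V heavy chain, 1.27-fold higher (interval 1.21 to 1.33). Prostate cancer susceptibility locus genes had a median of -0.00 (percentile 52.9), with 1 of 11 members, PRAC1, lower (1.52-fold, interval 1.18 to 1.96).

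**Figure D3:**
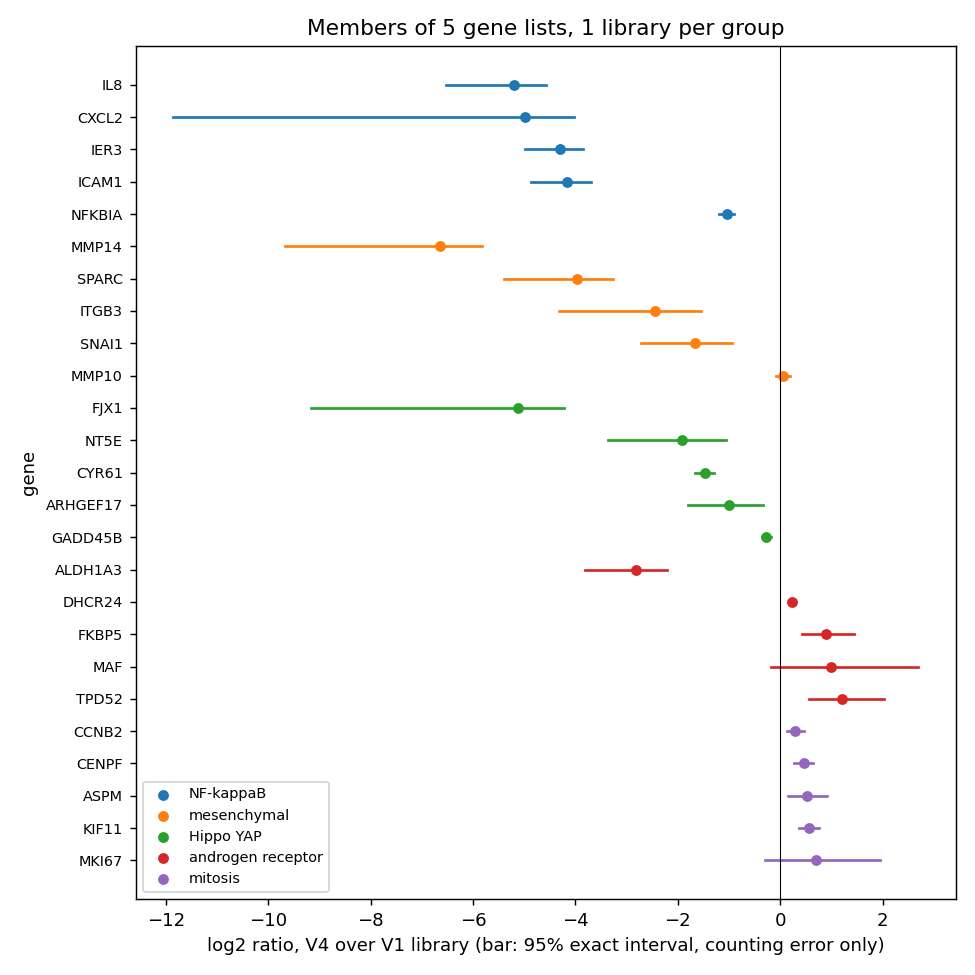
Points are log2 ratios of V4 over V1 for members of 5 gene lists, coloured by list, and bars are 95% exact intervals of counting error. NF-kappaB members such as IL8 (-5.20) lie left of 0, while the androgen receptor target TPD52 lies at 1.21 and the mitosis gene KIF11 at 0.57.

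The remaining lists had medians inside the random range. Those of p53 targets (0.06), cholesterol synthesis (0.03), apoptosis regulators (-0.00), lysosome and autophagy (-0.05), and reference genes (-0.00) had 0 members at least 1.5-fold apart. Splicing factors had a median of 0.11 (percentile 93.9). MYC and ribosome biogenesis genes stood at -0.04, replication-dependent histones at -0.11, fatty acid synthesis at -0.17, WNT genes at -0.16, NOTCH genes at 0.18, PI3K, AKT, FOXO and mTOR genes at 0.12, and amino acid response genes at 0.05. With a GC trend removed, the last 3 lists moved above the range: NOTCH at 0.33 (percentile 98.6), PI3K at 0.21 (percentile 98.4) and amino acid response at 0.11 (percentile 98.6). MYC itself was 1.37-fold lower (interval 1.27 to 1.49). The 7 lists with fewer than 5 kept members got no percentile. Among their most abundant members, the leukocyte marker CD68 was 1.48-fold lower (interval 1.05 to 2.09), the haemoglobin gene HBA1 1.32-fold lower (interval 1.00 to 1.74), the basal marker DST 2.16-fold higher (interval 1.16 to 4.17), the pigment cell gene GPR143 had 58 counts against 57, and the signal recognition particle RNA RN7SL2 was 1.29-fold lower (interval 1.22 to 1.36). Endothelial markers had 0 kept members.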

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

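Removing a transcript length or GC trend and keeping genes with 1 RefSeq transcript were chosen after seeing the data. The counts of 186 genes at least 2-fold higher and 379 lower in the V4 library stayed within 1.5 times under median-of-ratios, total-count and upper-quartile scaling, a prior count of 0.5, thinning, no condition on the interval, and either trend removed. They were 316 and 582 with no filter beyond 1 count, 12 and 58 at a mean CPM of at least 10, 486 and 628 at 1.5-fold, 38 and 179 at 3-fold, and 68 and 186 among genes with 1 RefSeq transcript. Each of these changed the number of genes eligible or the threshold itself. With a prior count of 8, which draws low counts toward a ratio of 1, 78 genes were higher. The MLPH log2 ratio of 0.09 was 0.17 with the GC trend removed, outside its counting interval, and the cause was not tested. Of the 14 lists below the random range, 14 stayed there under median-of-ratios, total-count scaling and a prior count of 0.5, 13 at a mean CPM of at least 10, 10 with either trend removed, 11 among genes with 1 RefSeq transcript and 8 against unmatched random lists. The 10 that stayed with the length trend removed were not all the same lists as the 10 that stayed with the GC trend removed. Of the 6 above it, 6 stayed under median-of-ratios, total-count scaling and a prior count of 0.5, 4 at a mean CPM of at least 10, 0 among genes with 1 RefSeq transcript (where 4 had too few members) and 4 against unmatched random lists. Of the 5 of them with transcript lengths, 3 stayed with the length trend removed and 2 with the GC trend removed, and 3 others moved above it with the GC trend removed. NF-kappaB, mesenchymal, Hippo YAP, immediate early and cytosolic ribosomal lists stayed below under all 8 settings. Among 208 named genes besides MLPH, no ratio of 1.5-fold or more with an interval that excluded 1 changed direction under the settings run. This is no check of those ratios. Scaling shifted log2 ratios by at most 0.035 and the length trend by -0.18 to 0.43, too little to turn a 1.5-fold ratio, and a prior count cannot turn one. Of the 208 ratios, 46 moved outside their counting interval with the length trend removed and 43 with the GC trend removed. Comparisons over the empty vector, the agreement of ratios over it, and separate repeat runs were not run. Most genes at least 2-fold apart had few counts, with a median of 40 counts in V1 for those lower and 29.5 in V4 for those higher, so depth limits the size of single ratios.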

Other observations

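The tests of transcript length, GC content, transcript number and pseudogenes were set before their results were seen, that of GC after its correlation with the ratio was known. Those of counting error and of cells of another type were chosen after the result was seen, as were the permutation within families, the interval on the pseudogene share and the leaving out of mitochondrially encoded genes, which had no length, from the trend tests.

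UCHL1, a ubiquitin hydrolase gene chosen after its values were seen, had 1933 counts in the V1 library and 34 in the V4 library, 57.6-fold lower (interval 41.1 to 83.5). Genes with 20 or more counts in V1 and 0 in V4 numbered 20, and the reverse numbered 0.

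Genes far lower in the V4 than in the V1 library formed a pattern of 1 direction, with 100 genes at least 5-fold lower and 6 at least 5-fold higher (ratios with a prior count of 2). Counting error is excluded, because simulated unchanged pairs gave at most 1 gene at least 5-fold lower against the 100 observed. The fitted transcript length trend ran from -0.18 to 0.43 on the log2 scale, too small to make a 2-fold gap on its own. The median log2 ratio of the genes at least 2-fold lower was -1.54 both before and after that trend was removed. A trend of this size could not have brought that median near 0, so the outcome of its removal was fixed in advance. Cells of another type in the V1 library may be a source: 2 of the 3 kept fibroblast markers, COL1A2 and COL3A1, were at least 2-fold lower in V4, but LUM was not, and the epithelial genes KRT7 and CLDN1 were lower as well. This source cannot be told apart from an effect of the plasmids, because each plasmid had 1 library.

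Of the lists lower in the V4 library, 12 had a median transcript length under that of kept genes (3376 bases), and of the 5 higher lists with lengths, 3 lay over it. Across 8431 genes with a length, the log2 ratio had a Spearman rho of 0.27 with transcript length and -0.33 with GC content, and across the 4987 of them with 200 or more counts 0.41 and -0.47, and genes are not independent replicates. With the length trend removed, 8 of 12 lists of short-transcript genes stayed below the random range and 3 of 5 lists with lengths above it. The trend in the length used here therefore does not alone account for those. That length was of the longest annotated transcript, such as 5620 bases for RPL28. Lengths of the transcripts present in these cells were not known, so a trend with them may remain and was not tested. With the GC trend removed, 11 of the 17 stayed outside on the same side. Each trend was removed alone, and the lists that moved inside were in part different ones. The antigen presentation, NF-kappaB, hypoxia, cytosolic ribosomal, immediate early and Hippo YAP lists stayed below the range both times. Of the 5 higher lists, the neuroendocrine markers alone stayed above it both times. Removing both trends together was not tested. For the lists that moved inside, such as nuclear-encoded respiratory chain genes (length) and mitosis genes (GC), a trend between the libraries may account for the shift, and an effect of the plasmids was not tested.

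Of 216 genes of essential families, 182 were in the table under their GENCODE v29 symbol, 100% of those with 1 curated RefSeq transcript and 75.4% of those with several. Of the 182, 7 had fewer than 3 counts in each library. PSMA4 and EIF4G1, a proteasome subunit and a translation initiation factor that dividing cells need, had 0 counts in each, and CCT7 had 1 and 2. Among 181 genes of 6 essential families, those with 1 curated RefSeq transcript had a median 7.36 times that of genes with several (417 against 56.6 CPM). The ratio ran from 3.81 to 35.2 in the 5 families that hold both kinds, and the 35.2 rests on 2 genes against 5 of the COP9 signalosome. A two-sided permutation test within families gave p = 1e-05, the smallest that 100000 permutations can give. A candidate explanation is that reads shared by several transcripts of a gene were left uncounted. Levels of genes with several transcripts, MLPH with 5 among them, may then be too low. The V4 over V1 ratio of MLPH may then be off as well, because the plasmids carry different transcripts of it, which was not tested. Whether reads shared with processed pseudogenes were left uncounted too was not settled. Of 73 genes of these families with no annotated processed pseudogene, 20.5% (15 genes, exact interval 12.0 to 31.6) lay under 10 CPM. Under 10% was predicted for this source, but the interval includes the 20% set as the limit against it. The 15 include EIF2AK4, EIF4E3 and EIF2D, whose need in dividing cells was not checked. Within the 73, the median was 407 CPM with 1 curated transcript (25 genes) and 42.3 CPM with several (48 genes). Pseudogenes alone therefore do not account for the gap by transcript number.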
